A study of Mus musculus with 4 samples.

How the data were processed

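Droplet-based single-cell RNA-seq libraries were made from mouse brain cells selected magnetically with an antibody against CD11b, per the labels. There were 4 libraries, 1 for each genotype, and the labels name microglia as the cell type. Age, sex, number of animals and dates are not given in the sources used here.

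The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 6.1.2, per the file headers. The genome build was mm10, per the submitters' processing notes. Each matrix lists 32285 genes. The lowest UMI total of a barcode was 500 or 501 in each library; filters beyond the barcode selection are not given in the sources used here. A few symbols of the fixed lists did not match the gene table and were not analysed here. Gene positions were taken from the GENCODE M21 annotation of the same build, which held all 221 named genes.

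Cells with 300 or more genes and at most 10% mitochondrial UMIs were kept, 7635, 5189, 5341 and 5174 of the wild-type, TERF2DN, APP/PS1 and APP/PS1;TERF2DN barcodes. Doublets were scored against simulated doublets within each library, and the highest-scoring cells were removed at 0.8% per 1000 cells: 466, 215, 228 and 214 cells. All libraries were then clustered together with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, and seed 1, without batch correction. Clusters were named from 17 fixed marker lists of 10 genes. A cluster with under 3 detected markers or led by markers of another class stayed unnamed, as did one of low UMI number with no marker of its class among its 10 leading genes. A class of cells is called X-like because its name rests on rebuilt clusters.

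Counts were summed over the cells of a class within each library and scaled to CPM, counts per 1e6 UMIs. Log2 ratios, list medians and the size threshold use CPM + 5, which understates differences of low genes. Ratios of single genes printed with an interval are plain CPM ratios without the added 5. A list member was measured at 10 CPM or more in at least 1 library, and counted as higher at a ratio of 1.25 or more and as lower at 0.8 or less. For lists in border macrophage-like cells the minimum was 50 CPM. Each list has its median, a 95% order-statistic interval over members and its percentile among 10000 random lists of the same size matched on mean expression, which describes these libraries and is no test. Sums have exact Poisson intervals, ratios exact conditional binomial intervals and shares Clopper-Pearson intervals. With 1 library per genotype no test was run, and no p-value is given. A total of 4 comparisons was made: APP/PS1 against wild-type, TERF2DN against wild-type, APP/PS1;TERF2DN against APP/PS1 and APP/PS1;TERF2DN against TERF2DN. The difference of both TERF2DN log2 ratios was also taken.

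The 22 state lists were homeostatic microglia, DAM stage 1 and stage 2, interferon response, MHC class I and II, proliferation, phagocytic receptors, amyloid-degrading proteases, lysosome, inflammatory cytokines, dissociation and immediate-early genes, senescence, TGF-beta signalling, cholesterol and lipid handling, glycolysis, oxidative phosphorylation, TREM2 to SYK signalling, complement, heat shock and unfolded protein, genotype checks and sex-linked genes. Lists, markers, thresholds and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 12 genes with the highest and the 12 with the lowest log2 ratio among those at 20 CPM or more in a compared library (8 each for the difference). It left out mitochondrial, cytosolic ribosomal, haemoglobin and sex-linked genes and unnamed gene models. It added up to 4 members of each list with the largest ratios, the genotype check genes and a fixed set including Trem2, Apoe, Cst7, P2ry12, Cd36 and Il1b. In endothelial-like cells it took Terf2 and the senescence list. A few of the genes taken are not reported here. Plin2, Igf1 and other genes that the rule takes in 1 comparison are given in others as well. Elane, Prtn3, Klf9 and Ddit4 and the border macrophage genes were chosen after their values were seen.

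For the DAM-high share each microglia-like cell was thinned at random to 2000 UMIs, and shallower cells were left out. Alternatives were no doublet removal, no cell filter, 1000 genes and 5% mitochondrial UMIs, resolution 0.5, clustering by library, gating cell by cell, size factors, mean CPM per cell, thinning before summing, pseudocounts of 1 and 20 CPM, member minimums of 50 CPM and of any count, members of no other list, removal of the 25% of cells highest in immediate-early genes, and other thresholds of the DAM-high share. A further 3 were chosen after seeing the data: counting a low-UMI cluster as microglia-like, leaving out the cycling cluster, and equal cluster mixes.

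The computation of ratios and intervals was tested on simulated counts. For APP/PS1;TERF2DN against APP/PS1, with 5246 genes and 50 changed at each size, a true log2 change of 1 was estimated at 0.95 and one of -1 at -0.87, and 94.6% of intervals held the true ratio. For TERF2DN against wild-type, with 5851 genes, the estimates were 0.93 and -0.88. For APP/PS1 against wild-type, with 5922 genes, they were 0.92 and -0.86, and for APP/PS1;TERF2DN against TERF2DN, with 5930 genes, 0.95 and -0.86. No unchanged gene passed the size threshold in these simulations once the known shift that the changed genes cause was subtracted. The estimates had that shift subtracted too. Real CPM ratios had no such correction, so the simulations do not gauge a shift of all genes by CPM. They drew Poisson counts only, without variation between animals or libraries, so they give no rate of false calls between genotypes. Software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.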

Results

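Single-cell transcriptomes were read from brain cells selected with an antibody against the myeloid surface protein CD11b, in mice of 4 genotypes with 1 library each. The genotypes were wild-type, TERF2DN, APP/PS1 and the combination APP/PS1;TERF2DN. APP/PS1 mice carry transgenes that make them deposit amyloid in the brain. TERF2DN is a dominant-negative form of the telomere-binding protein TERF2, which the series title ties to senescence of endothelial cells. The questions were how microglia differ with amyloid, how they differ with TERF2DN, and whether TERF2DN goes with another microglial state in the presence of amyloid. No genotype had replicates, so every comparison below is between 2 libraries. All intervals are 95%. Those of sums, ratios and shares cover counting error only, and those of list medians the spread over member genes.

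The wild-type library held 46255914 UMIs in 7950 barcodes, and the TERF2DN library 30702262 UMIs in 5565 barcodes. The APP/PS1 library held 37981635 UMIs in 5599 barcodes, and the APP/PS1;TERF2DN library 37061388 UMIs in 5406 barcodes. Median UMIs per barcode were 5130.5, 4894, 5492 and 5509 in the same order. After filtering and removal of predicted doublets, 7169, 4974, 5113 and 4960 cells remained. Clusters with microglial markers such as P2ry12 and Tmem119 made up most of them. These microglia-like cells were 75.7% of wild-type cells (74.6% to 76.6%), 71.2% of TERF2DN cells (69.9% to 72.4%), 84.1% of APP/PS1 cells (83.1% to 85.1%) and 84.4% of APP/PS1;TERF2DN cells (83.4% to 85.4%), by exact Clopper-Pearson intervals. The magnetic selection sets these shares. They also depend on 1 cluster of low UMI number, left unnamed, which held 989, 921, 272 and 335 cells; with it counted as microglia-like, the shares were 89.5%, 89.7%, 89.4% and 91.2%. Summed microglia-like counts reached 33355936, 22542511, 31989056 and 31186360 UMIs, from cells with median depths of 5474, 5664, 6253 and 6188 UMIs.

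Other cell classes were small. Border macrophage-like cells, led by Mrc1 and Pf4, were 5.41%, 4.32%, 1.76% and 2.68% of cells. Neutrophil-like cells were 0.990%, 0.804%, 0.215% and 0.423%, and monocyte-like cells 0.600%, 0.563%, 0.0782% and 0.141%. There were 31, 28, 31 and 37 endothelial-like cells and 13, 8, 15 and 3 mural-like cells. Astrocyte-like cells of low depth numbered 11, 10, 250 and 116. In the APP/PS1 library these held Cst7, a microglial activation gene, at 1024 CPM, beside 1364 CPM in the microglia-like cells.

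Genes tied to the transgenes were examined first. The series title names the APPswe/PS1dE9 model, in which the mouse prion protein promoter is generally used for the transgenes; the construct is not given in the sources used here. Prnp, the gene of that protein, stood at 2.67 CPM in wild-type, 2.57 CPM in TERF2DN, 27.2 CPM in APP/PS1 and 23.3 CPM in APP/PS1;TERF2DN microglia-like cells. The ratio of APP/PS1 to wild-type was 10.2 (8.20 to 12.8). App differed little, at 119, 131, 142 and 144 CPM, and human transcripts were not counted against a mouse reference as such. Terf2 in microglia-like cells was similar in all libraries, at 18.3, 20.1, 15.7 and 17.1 CPM. In endothelial-like cells Terf2 had 8, 16, 2 and 13 UMIs, or 22.5, 83.5, 10.96 and 64.0 CPM. The TERF2DN to wild-type ratio there was 3.72 (1.502 to 10.04), and that of APP/PS1;TERF2DN to APP/PS1 was 5.84 (1.32 to 53.3). Whether these 3' reads come from the transgene or from the mouse gene is not known from the counts. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 4 libraries, with Ddx3y at 65.5, 68.3, 48.9 and 48.5 CPM.

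Endothelial-like cells also carried senescence genes. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 376 CPM in wild-type (315 to 446), 439 CPM in TERF2DN (350 to 543), 663 CPM in APP/PS1 (550.1 to 792) and 1211 CPM in APP/PS1;TERF2DN (1064 to 1372). The ratio of APP/PS1;TERF2DN to APP/PS1 was 1.83 (1.46 to 2.29), and that of TERF2DN to wild-type was 1.17 (0.877 to 1.54). Igfbp4, a secreted binder of insulin-like growth factors, had 4, 1, 3 and 37 UMIs. Cdkn2b, another cell cycle inhibitor, had 23, 13, 5 and 14 UMIs, and Cdkn2a had 0, 0, 1 and 0. Other members were lower in APP/PS1;TERF2DN than in APP/PS1: the stress gene Gadd45a had 7 UMIs in APP/PS1 and 0 in APP/PS1;TERF2DN, Phlda3 6 and 2, Trp53 7 and 5, Ccng1 3 and 1, and Cdkn2d 10 and 9. Ccnd1 stood at 208 and 133 CPM and Hmgb1 at 811 and 674 CPM. Bax, at 93.1 and 153 CPM, Mdm2, with 6 and 8 UMIs, and Glb1, with 2 and 4, were higher. Lmnb1, Timp1, Mmp12 and Il6 had at most 4 UMIs in any library, and Gdf15 had none. In this comparison only the intervals of Cdkn1a, Igfbp4 and Gadd45a left out a ratio of 1. With at most 37 cells per library, these sums can rest on a few cells.

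Amyloid alone was examined by comparing APP/PS1 with wild-type microglia-like cells. Genes of disease-associated microglia (DAM), the lipid-handling and phagocytic state seen around plaques, were far higher in the APP/PS1 library. All 24 measured genes of the DAM stage 2 list were higher, with a median log2 ratio of 2.32 (1.21 to 3.43 over members). Cst7, a cysteine protease inhibitor, stood at 16.3 CPM in wild-type and 1364 CPM in APP/PS1, a ratio of 83.6 (76.8 to 91.2). Gpnmb, a lysosomal glycoprotein, stood at 3.69 and 364 CPM, the growth factor Igf1 at 3.15 and 311 CPM, and the fatty acid binder Fabp5 at 27.7 and 916 CPM. Homeostatic genes of resting microglia were lower: 21 of 25 were lower and none was higher, with a median of -0.93 (-1.22 to -0.72).

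Within the homeostatic list, the purinergic receptor gene P2ry12 stood at 1763 CPM in wild-type and 756 CPM in APP/PS1 cells. Tmem119 stood at 879 and 318 CPM, Ecscr at 289 and 84.9 CPM, and Crybb1 at 523 and 159 CPM. The fractalkine receptor gene Cx3cr1 was at 3136 and 1908 CPM. All 7 DAM stage 1 genes were higher (median 1.18). Among them were the lipid carrier Apoe at 3158 and 29347 CPM, the lysozyme gene Lyz2 at 855 and 2730 CPM, and the signalling adaptor Tyrobp at 2775 and 6429 CPM. The phagocytic receptor Trem2, a DAM stage 2 gene, stood at 2454 and 5637 CPM. Other members of that list were the integrin gene Itgax at 13.2 and 250.5 CPM, the matrix protein Spp1 at 217 and 2595 CPM, the lipase Lpl at 40.1 and 459 CPM, and the receptor kinase Axl at 9.50 and 78.4 CPM. Outside the lists, Hpse, Dkk2 and Baiap2l2 were among the 12 genes with the highest ratios. Hpse, which encodes heparanase, stood at 0.2998 and 70.2 CPM, Dkk2 at 0.240 and 64.5 CPM, and Baiap2l2 at 0.510 and 64.7 CPM. Pdlim4, at 93.6 and 26.8 CPM, and Bank1, at 48.9 and 13.1 CPM, were among the lowest.

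The other measured lists gave both directions by CPM. MHC class II genes, which present antigen to T cells, had a median of 3.25, with 4 of 6 higher. Among them, H2-Aa stood at 15.9 and 332 CPM and the invariant chain Cd74 at 101 and 1263 CPM. With microglia gated cell by cell, which takes in more MHC class II RNA in wild-type, the median was 0.82, with H2-Aa at 145 and 375 CPM and Cd74 at 553 and 1396 CPM. MHC class I genes had a median of 0.37, with 6 of 12 higher and H2-D1 at 577 and 1215 CPM. Interferon response genes had a median of 0.59, with 10 of 15 higher and Ifi27l2a at 63.9 and 282 CPM. Glycolysis genes had a median of 0.95, with 12 of 16 higher and Tpi1 at 88.8 and 217 CPM. Oxidative phosphorylation genes had a median of 0.42, with 18 of 24 higher and Ndufa1 at 92.1 and 332 CPM. Cholesterol and lipid handling genes had a median of 0.77, with 13 of 19 higher and Fabp3 at 2.31 and 89.8 CPM. Lysosomal genes had a median of 0.39, with 17 of 30 higher, and the cathepsin gene Ctsl stood at 1332 and 3604 CPM. TGF-beta signalling genes, which maintain homeostatic microglia, had a median of -0.47, with 10 of 14 lower and Tgfbr1 at 1106 and 576 CPM. The TREM2 to SYK list had a median of -0.58, with Trem2, Tyrobp and Hcst higher and 10 of 16 lower, among them Dok3 at 35.3 and 13.2 CPM.

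Phagocytic receptor genes split, 9 of 22 higher and 7 lower (median 0.13), with Cd36 at 0.989 and 0.969 CPM. Amyloid-degrading protease genes had a median of 0.38, with 3 of 6 higher and the urokinase gene Plau at 20.9 and 113 CPM. Senescence genes had a median of 0.20, with 7 of 15 higher and 3 lower. Their member Cdkn2a stood at 2.49 and 16.1 CPM. Inflammatory cytokine genes had a median of -0.27, near the all-gene median of -0.28, with 3 of 12 higher and 5 lower. The chemokine Ccl3 was at 71.2 and 510.1 CPM, Il1a at 53.7 and 26.4 CPM, and Il1b at 5.01 and 9.91 CPM. Dissociation and immediate-early genes had a median of -0.09, heat shock and unfolded protein genes -0.04, proliferation genes -0.05 and complement genes -0.19. The neutrophil genes S100a8 and S100a9 were higher in the wild-type library, at 207 and 6.25 CPM and at 218 and 2.44 CPM. The highest 54 of its microglia-like cells held 94.9% of the S100a8 UMIs. A single cell held 3778 of its 6911 S100a8 UMIs, and a single cell 3809 of its 7263 S100a9 UMIs. Without the cycling cluster of microglia-like cells, S100a8 stood at 14.99 and 6.28 CPM and S100a9 at 16.9 and 2.47 CPM.

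Scaling matters here. The median log2 ratio of all genes was -0.28 by CPM and 0.01 by median-of-ratios size factors. Relative to that shift, DAM stage 2 stood at 2.62 with 24 of 24 higher, and the homeostatic list at -0.60 with 20 of 25 lower and 1 higher. By size factors 13 of 15 interferon genes, 11 of 12 MHC class I genes, 6 of 6 MHC class II genes, 22 of 24 oxidative phosphorylation genes and 15 of 19 lipid genes were higher. TGF-beta genes then had 5 of 14 lower and 1 higher. The TREM2 to SYK list had 6 of 16 lower and 5 higher, phagocytic receptors 12 of 22 higher and 3 lower, and senescence genes 9 of 15 higher and 1 lower. Proliferation genes then had 4 of 12 higher and none lower, protease genes 3 of 6 higher and none lower, and heat shock genes 6 of 14 higher and 1 lower. Cytokine genes had 3 of 12 higher and 4 lower by size factors, with a median of -0.00098. Complement genes had 2 of 9 lower by CPM and none by size factors, and their median turned from -0.19 to 0.13. The medians of proliferation, dissociation and heat shock genes turned positive as well, to 0.24, 0.17 and 0.26. Different clusters hold most of the microglia-like class in each library: clusters 4, 6, 7 and 11, with Gpnmb, Lpl, Cst7 or Spp1 among their leading genes, each had over 90% of their cells in the APP/PS1 and APP/PS1;TERF2DN libraries, the rule by which they were picked after clustering. Among 10000 random lists matched on expression, the DAM stage 2 median lay at percentile 100 and the homeostatic median at percentile 0.

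**Figure D1:**
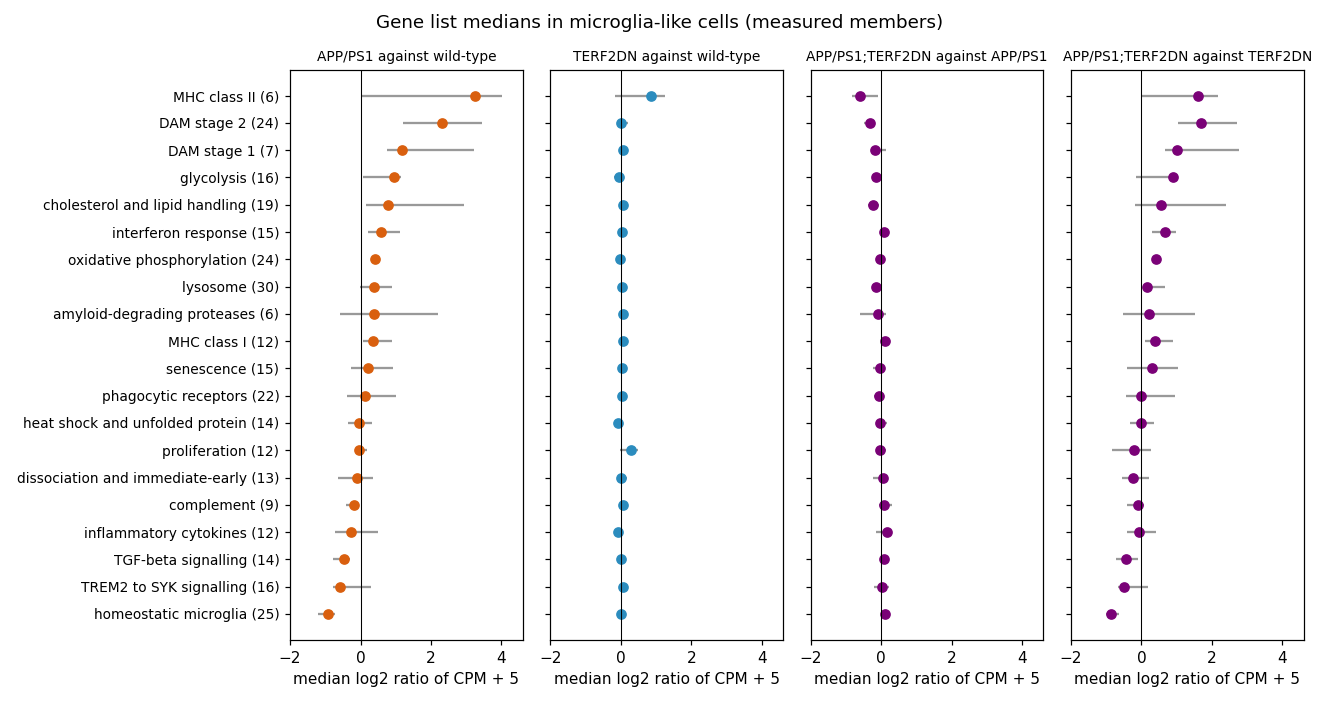
Median log2 ratio of CPM + 5 (horizontal axis) of each gene list in microglia-like cells, 1 panel per comparison, with the number of measured members in brackets and 95% intervals of the median over members as lines. DAM stage 2 genes lay at 2.32 in APP/PS1 against wild-type and at -0.32 in APP/PS1;TERF2DN against APP/PS1, while homeostatic genes lay at -0.93 and 0.11; by size factors instead of CPM the complement median in the first panel is 0.13 instead of -0.19.

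TERF2DN without amyloid was examined by comparing TERF2DN with wild-type microglia-like cells. These libraries differed little: the homeostatic list had a median of -0.01 with 25 of 25 genes neither higher nor lower, and DAM stage 2 a median of -0.00 with 3 of 24 higher and 1 lower. P2ry12 stood at 1763 CPM in wild-type and 1714 CPM in TERF2DN, Tmem119 at 879 and 853 CPM, Trem2 at 2454 and 2366 CPM, Tyrobp at 2775 and 2669 CPM, and Cx3cr1 at 3136 and 3451 CPM. Within DAM stage 2, Cst7 was higher in the TERF2DN library, at 16.3 and 29.4 CPM, a ratio of 1.80 (1.61 to 2.02). The clusters 4, 6, 7 and 11, picked by their cells from the APP/PS1 and APP/PS1;TERF2DN libraries, held 0.903% of wild-type and 1.497% of TERF2DN microglia-like cells. Igf1 at 3.15 and 5.99 CPM and Itgax at 13.2 and 18.0 CPM were also higher, Itgax by CPM only and not by size factors, while Spp1 was lower, at 217 and 97.0 CPM. After thinning, 1.16% of wild-type and 1.44% of TERF2DN cells held an Spp1 UMI (0.885% to 1.48% and 1.07% to 1.90%), so the share of positive cells was not lower. Apoe stood at 3158 and 3668 CPM.

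MHC class II genes were higher in the TERF2DN library, with 4 of 6 higher and a median of 0.85. H2-Aa stood at 15.9 and 45.03 CPM, H2-Eb1 at 18.5 and 40.7 CPM, H2-Ab1 at 29.3 and 55.9 CPM, and Cd74 at 101 and 190 CPM. Few cells held these UMIs: the highest 35 of 3541 TERF2DN cells held 95.2% of the H2-Aa UMIs. Without the cycling cluster of microglia-like cells, 42 in wild-type and 34 in TERF2DN, H2-Aa stood at 9.14 and 16.2 CPM, H2-Eb1 at 10.9 and 13.7 CPM, H2-Ab1 at 20.02 and 28.98 CPM and Cd74 at 79.97 and 119.6 CPM, and the list median was 0.34. Gated cell by cell, none of these genes was past the size threshold, with H2-Aa at 145 and 149.7 CPM and Cd74 at 553 and 572 CPM. Proliferation genes had a median of 0.28, with 5 of 12 higher by CPM and 3 by size factors, and Cenpf, which encodes a kinetochore protein, stood at 7.94 and 19.7 CPM. The make-up of the cycling cluster differed as well. It held the neutrophil precursor genes Elane and Prtn3 at 718 and 759 CPM in wild-type but at 0 and 14.1 CPM in TERF2DN. Higher single genes were the histone gene Hist1h2ap at 25.2 and 46.1 CPM, the interferon-induced Ifi27l2a at 63.9 and 94.98 CPM, Gstp1 at 21.8 and 31.5 CPM, and Psat1, of serine synthesis, at 16.4 and 23.9 CPM. Lower single genes were Arl6ip5 at 83.4 and 47.1 CPM and the tubulin genes Tuba1a, at 105 and 80.7 CPM, and Tubb2b, at 31.2 and 23.1 CPM. The neutrophil genes S100a8, S100a9, Camp and Ngp were the 4 genes with the lowest ratios. These rest largely on single wild-type cells. The highest cell held 3778 of 6911 S100a8, 3809 of 7263 S100a9, 1549 of 1900 Camp and 613 of 1145 Ngp UMIs. S100a8 stood at 207 and 15.04 CPM, but at 14.99 and 14.97 CPM without the cycling cluster.

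In the same comparison the other lists had medians close to 0: interferon response 0.04, MHC class I 0.05, DAM stage 1 0.05, phagocytic receptors 0.02, lysosome 0.03, TREM2 to SYK 0.06, complement 0.06, proteases 0.06, senescence 0.03, lipid handling 0.06, TGF-beta -0.01, glycolysis -0.05, oxidative phosphorylation -0.03, dissociation 0.02, cytokines -0.09 and heat shock -0.08. Of 22 phagocytic receptor genes, only Itgax was higher by CPM, none was by size factors, and none was lower. Il1b stood at 5.01 and 3.95 CPM, and the scavenger receptor gene Cd36 at 0.989 and 1.29 CPM. The all-gene median was 0.01. At 1 library each, a difference between the animals sampled cannot be separated from one between genotypes.

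TERF2DN with amyloid was examined by comparing APP/PS1;TERF2DN with APP/PS1 microglia-like cells. The DAM program was lower in the APP/PS1;TERF2DN library: 12 of 24 DAM stage 2 genes were lower and none was higher, with a median of -0.32 (-0.48 to -0.26) that was under all 10000 random lists. Spp1 stood at 2595 CPM in APP/PS1 and 1396 CPM in APP/PS1;TERF2DN, a ratio of 0.538 (0.532 to 0.544). Gpnmb stood at 364 and 204 CPM, Itgax at 250.5 and 153 CPM, and Fabp5 at 916 and 577 CPM. Cst7 was at 1364 and 1026 CPM, Lpl at 459 and 324 CPM, Axl at 78.4 and 54.7 CPM, and Trem2 at 5637 and 4594 CPM. Homeostatic genes had a median of 0.11 (0.05 to 0.17), with Crybb1 as the 1 of 25 past the size threshold, at 159 and 249 CPM. Tmem119 was at 318 and 394 CPM, P2ry12 at 756 and 849 CPM, and Cx3cr1 at 1908 and 1916 CPM.

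With the cluster mixes of both libraries set equal, the DAM stage 2 median was -0.14 and the homeostatic median -0.07, opposite in sign to its main value; clusters 4, 6, 7 and 11 held 61.3% of APP/PS1 and 50.1% of APP/PS1;TERF2DN microglia-like cells. By size factors 15 of 24 DAM stage 2 genes were lower. DAM stage 1 genes had a median of -0.18, none of 7 past the threshold, with Apoe at 29347 and 24914 CPM and Tyrobp at 6429 and 5456 CPM. MHC class II genes had a median of -0.60, with 4 of 6 lower. H2-Aa stood at 332 and 192 CPM and Cd74 at 1263 and 873 CPM. Lipid handling genes had a median of -0.24, with 5 of 19 lower, among them Fabp3 at 89.8 and 61.1 CPM and Apoc4 at 44.95 and 29.0 CPM, and with Plin2, a lipid droplet coat gene, at 63.7 and 81.9 CPM. The lysosome list had a median of -0.13, with 2 of 30 lower: Atp6v0d2 at 54.8 and 34.0 CPM and Atp6v1a at 87.1 and 64.1 CPM, both subunits of the proton pump. Glycolysis genes had a median of -0.15, with the glucose transporter Slc2a1 at 36.8 and 26.2 CPM.

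Phagocytic receptor genes had a median of -0.06, with 1 of 22 higher and 2 lower. The lipopolysaccharide co-receptor Cd14 was the higher one, at 336 and 489 CPM, and Itgax and Axl the lower ones; Cd36 stood at 0.969 and 1.92 CPM. Of the protease genes, Plau was lower, at 113 and 72.1 CPM, and the list median was -0.10. In the TREM2 to SYK list (median 0.03) 3 of 16 genes were higher: Dok3 at 13.2 and 19.6 CPM, Inpp5d at 248 and 324 CPM and Pik3r1 at 65.8 and 84.9 CPM. Cytokine genes had a median of 0.17, with Ccl3 lower at 510.1 and 363 CPM, Ccl9 higher at 25.2 and 34.3 CPM, and Il1b at 9.91 and 9.88 CPM. Complement genes had a median of 0.09, and the anaphylatoxin receptor C5ar1 was higher at 30.1 and 48.3 CPM. The medians were 0.07 for interferon response, 0.12 for MHC class I, 0.08 for TGF-beta, -0.04 for oxidative phosphorylation, -0.04 for senescence, -0.02 for proliferation, 0.06 for dissociation and -0.05 for heat shock genes.

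The highest single genes in this comparison were Tsc22d3, at 8.003 and 33.2 CPM, and Fkbp5, at 32.4 and 91.0 CPM, both induced by glucocorticoids. In wild-type and TERF2DN, Tsc22d3 stood at 25.9 and 22.8 CPM and Fkbp5 at 47.7 and 49.2 CPM, above APP/PS1. Their ratios were 4.15 (3.62 to 4.78) and 2.81 (2.62 to 3.02). They were followed by the sulfotransferase Sult1a1 at 40.0 and 81.8 CPM, the cyclin gene Ccnd3 at 26.6 and 55.1 CPM, the PI3K inhibitor Pik3ip1 at 10.8 and 22.0 CPM and the cytokine receptor Lifr at 24.7 and 44.3 CPM. The mitochondrial carrier Ucp2 stood at 400.0 and 622 CPM and the glutamine synthetase gene Glul at 139 and 214 CPM. Besides DAM genes, the lowest included Flt1 at 80.3 and 41.0 CPM, Hpse at 70.2 and 36.7 CPM, Il4i1 at 48.5 and 25.7 CPM and Mamdc2 at 54.1 and 31.7 CPM. The all-gene median was 0.01.

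**Figure D2:**
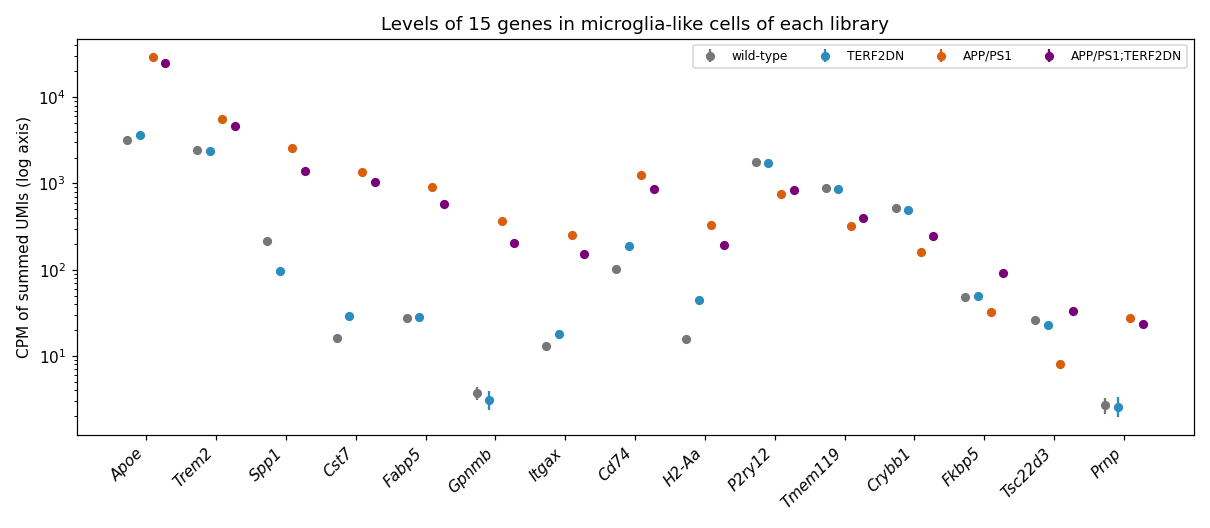
CPM of 15 genes (log axis) in summed microglia-like counts of the 4 libraries, with exact Poisson 95% intervals as bars. Spp1 lay at 217, 97.0, 2595 and 1396 CPM in wild-type, TERF2DN, APP/PS1 and APP/PS1;TERF2DN, P2ry12 at 1763, 1714, 756 and 849 CPM, and Fkbp5 at 47.7, 49.2, 32.4 and 91.0 CPM.

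Amyloid in the presence of TERF2DN was examined by comparing APP/PS1;TERF2DN with TERF2DN microglia-like cells. As without TERF2DN, all 24 DAM stage 2 genes were higher, here with a median of 1.70 (1.02 to 2.72), and 21 of 25 homeostatic genes were lower, with a median of -0.85 (-1.01 to -0.63). Cst7 stood at 29.4 CPM in TERF2DN and 1026 CPM in APP/PS1;TERF2DN, Gpnmb at 3.06 and 204 CPM, Spp1 at 97.0 and 1396 CPM, and Wfdc17, a secreted protease inhibitor gene, at 16.0 and 161 CPM. Ecscr stood at 293 and 97.2 CPM, P2ry12 at 1714 and 849 CPM, and Bank1 at 44.7 and 14.2 CPM. DAM stage 1 genes had a median of 1.01, with 7 of 7 higher, and Apoe stood at 3668 and 24914 CPM.

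In that comparison MHC class II genes had a median of 1.61 (4 of 6 higher, Cd74 at 190 and 873 CPM), interferon genes 0.68 (11 of 15 higher, Ifitm3 at 54.9 and 136 CPM) and MHC class I genes 0.38 (6 of 12 higher, B2m at 1014 and 2048 CPM). Gated cell by cell, the MHC class II median was 0.21, with Cd74 at 572 and 937 CPM and H2-Eb1 at 176 and 146 CPM, lower in APP/PS1;TERF2DN; without the cycling cluster it was 2.69. Glycolysis genes had a median of 0.90 (12 of 16 higher, Ldha at 101 and 220 CPM), oxidative phosphorylation genes 0.41 (20 of 24 higher), and lipid genes 0.54 (11 of 19 higher, Lpl at 45.4 and 324 CPM). The medians were 0.16 for lysosome, 0.21 for protease, 0.29 for senescence, -0.01 for phagocytic receptor and -0.06 for cytokine genes. TGF-beta genes had a median of -0.43 (10 of 14 lower, Eng at 49.0 and 22.9 CPM) and TREM2 to SYK genes -0.50 (11 of 16 lower, Pik3cd at 62.1 and 33.6 CPM). Proliferation genes had a median of -0.22, dissociation genes -0.23, complement genes -0.10 and heat shock genes -0.00. Cd14 stood at 161 and 489 CPM, Il1b at 3.95 and 9.88 CPM, and Prnp at 2.57 and 23.3 CPM.

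Here too the all-gene median was -0.29 by CPM and 0.01 by size factors. By size factors the DAM stage 2 median was 2.0004 with 24 of 24 higher, and the homeostatic median -0.51 with 17 of 25 lower and 1 higher. The same scaling gave 14 of 15 interferon, 10 of 12 MHC class I, 6 of 6 MHC class II, 23 of 24 oxidative phosphorylation and 23 of 30 lysosomal genes higher. TGF-beta genes then had 3 of 14 lower, and the TREM2 to SYK list had 5 of 16 lower and 5 higher. Between CPM and size factors, the genes higher and lower went from 8 and 8 to 11 and 3 of 22 phagocytic receptors, from 3 and 3 to 5 and 1 of 12 cytokines, from 7 and 5 to 9 and 0 of 15 senescence genes, and from 2 and 5 to 4 and 4 of 12 proliferation genes. They went from 1 and 5 to 4 and 0 of 13 dissociation genes, from 3 and 4 to 7 and 1 of 14 heat shock genes, from 0 and 2 to 3 and 1 of 9 complement genes, and from 11 and 4 to 12 and 1 of 19 lipid genes. Of the glycolysis genes 2 were lower by CPM and none by size factors, and of the proteases 1 and none. The complement median was 0.23, the proliferation median 0.05, the dissociation median 0.11, the cytokine median 0.24, the phagocytic receptor median 0.32 and the heat shock median 0.32 by size factors, each opposite in sign to its CPM value.

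A score per cell gave the share of DAM-high microglia-like cells, with every cell thinned to 2000 UMIs and the threshold of 34 DAM stage 2 UMIs set at the 95th percentile of wild-type cells. The share was 4.93% in wild-type (4.36% to 5.54%), near 5% by construction, 4.45% in TERF2DN (3.78% to 5.20%), 56.8% in APP/PS1 (55.2% to 58.3%) and 44.5% in APP/PS1;TERF2DN (42.9% to 46.1%). The mean score of the DAM-high cells was 45.6, 49.7, 76.3 and 66.1 UMIs. Cells under 2000 UMIs were left out, 145, 146, 437 and 309 in the same order. Without thinning, as a share of each cell's UMIs, the DAM-high shares were 5.01%, 5.06%, 60.0% and 47.2%. The class is a range of a score and not a cell type, and 292, 146, 327 and 352 cells lay within 3 UMIs of the threshold. In endothelial-like cells, which should lack the program, none of 30, 28, 29 and 30 cells passed it; the median depths of that class were 6258, 6234.5, 5659 and 4805 UMIs. Among neutrophil-like cells, which should lack it too, 1 of 69, 0 of 36, 1 of 11 and 1 of 20 cells passed it. Among border macrophage-like cells, 5% passed it in APP/PS1 and 3.19% in APP/PS1;TERF2DN.

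**Figure D3:**
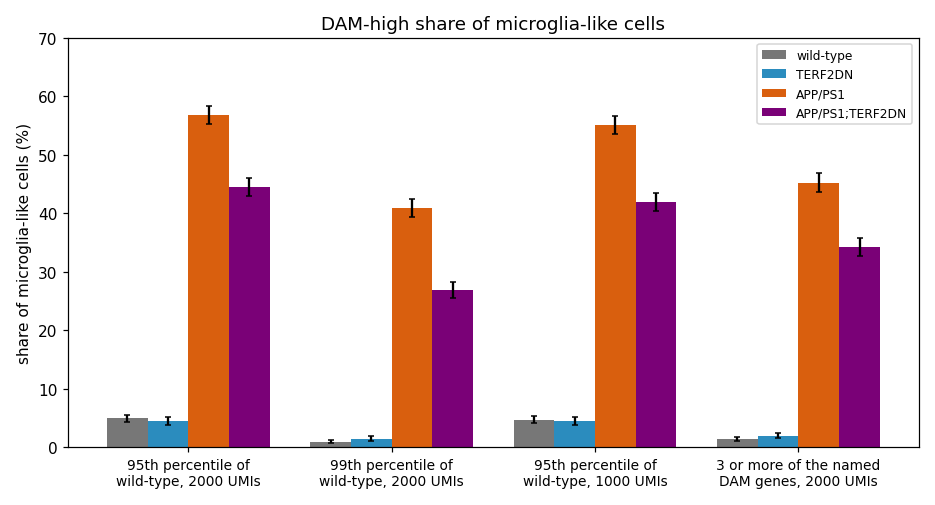
Share of microglia-like cells (vertical axis, percent) that passed 4 definitions of DAM-high, as bars from 0 with exact Clopper-Pearson 95% intervals, for the 4 libraries. In the first group of bars the shares were 4.93%, 4.45%, 56.8% and 44.5%, and with the 99th percentile as threshold 0.871%, 1.35%, 40.9% and 26.9%.

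Both TERF2DN comparisons were then set against each other. The log2 ratio with amyloid minus that without had a median of -0.31 over DAM stage 2 genes (11 of 24 lower, none higher), -1.45 over MHC class II genes, -0.31 over lipid genes (9 of 19 lower, 1 higher) and 0.16 over homeostatic genes (2 of 25 higher). It was 0.25 over cytokine genes (4 of 12 higher, 1 lower), -0.20 over proliferation genes (4 of 12 lower), -0.16 over lysosomal genes (4 of 30 lower), -0.13 over phagocytic receptors (2 of 22 higher, 4 lower), -0.11 over senescence genes (1 of 15 higher, 4 lower), -0.18 over DAM stage 1 genes (2 of 7 lower), -0.17 over proteases (2 of 6 lower) and 0.14 over complement genes (1 of 9 higher). The remaining lists, genotype checks aside, lay between -0.09 and 0.06. Among the cytokines, the difference was 0.56 for Ccl5, 0.51 for Ccl9, 0.42 for Il18 and -0.52 for Ccl3. The difference was -1.10 for Cst7, -1.03 for Itgax, -0.71 for Gpnmb, 1.71 for Tsc22d3 and 1.32 for Fkbp5. Of the genes named in every comparison, Spp1 was lower past the size threshold in both TERF2DN libraries than in their controls, and its difference was 0.23. Trem2 and Tyrobp were also lower in both, but within that threshold.

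In the mouse genome build mm10, Cst7 (ENSMUSG00000068129) lies on chromosome 2 from 150570415 to 150578944 and Spp1 (ENSMUSG00000029304) on chromosome 5 from 104435118 to 104441050. Apoe (ENSMUSG00000002985) lies on chromosome 7 from 19696109 to 19699188, Trem2 (ENSMUSG00000023992) on chromosome 17 from 48346401 to 48354147, and P2ry12 (ENSMUSG00000036353) on chromosome 3 from 59216272 to 59262871. Fkbp5 (ENSMUSG00000024222) lies on chromosome 17 from 28399094 to 28517527 and Tsc22d3 (ENSMUSG00000031431) on chromosome X from 140539528 to 140600659. Terf2 (ENSMUSG00000031921) lies on chromosome 8 from 107069400 to 107096547.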

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

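The test of marker-bearing cells for MHC class II genes in the TERF2DN library, and the settings without the cycling cluster, were chosen after the results were seen. The results below stood out because the log2 ratio of a TERF2DN library to its control was positive in one background and negative in the other; the differences themselves were not tested, since each rests on 4 single libraries.

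The difference, with amyloid minus without, was -2.03 for H2-Aa, -1.79 for H2-Eb1, -1.49 for H2-Ab1 and -1.40 for Cd74. Without the cycling cluster these were -1.32, -1.0009, -1.06 and -1.05, and gated cell by cell -0.83, -0.86, -0.62 and -0.62; gated, the log2 ratio of H2-Ab1 in TERF2DN against wild-type was -0.0462. Both DAM genes Cst7 and Itgax were higher in TERF2DN than in wild-type and lower in APP/PS1;TERF2DN than in APP/PS1, with differences of -1.10 and -1.03. The differences were -0.77 for Gstp1 and 0.81 for Ccnb1ip1. For Mki67 and Hist1h2ap, genes of dividing cells, they were -0.75 and -1.15, and that of Hist1h2ap was -1.31 without the cycling cluster; Mki67 leads that cluster and is near 0 CPM outside it, so that setting cannot speak to it. S100a8 and S100a9 had differences of 4.02 and 4.21, and of 0.27 and 0.86 without the cycling cluster. A single wild-type cell held 3778 of the 6911 S100a8 UMIs of microglia-like cells, and a single cell 3809 of the 7263 S100a9 UMIs. In wild-type the cycling cluster of 42 cells held S100a8 at 11790 CPM and the neutrophil precursor genes Elane and Prtn3 at 718 and 759 CPM. In APP/PS1;TERF2DN it held them at 1371 and 839 CPM and in APP/PS1 at 0 CPM, so values of dividing cells in the APP/PS1;TERF2DN library are mixed with such cells too.

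In the TERF2DN library, the median log2 ratio of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 to wild-type was 0.92. Cells of another antigen-presenting type within the microglia-like class may account for it, and this cannot be told apart from a difference in microglia: without cells holding 2 or more markers of border macrophages, monocytes, dendritic cells or B cells, 51.8% of wild-type and 57.0% of TERF2DN microglia-like cells, the median was 0.82, but the median level left of the 4 genes was 9.84 CPM in wild-type, for which the test was set to open after its value was seen. The 34 TERF2DN cells of the cycling cluster held H2-Aa at 1325 CPM, and without that cluster its log2 ratio was 0.59; with cells gated one by one, which let in cells of high MHC class II level, it was 0.04. Free RNA could not be judged. In pooled endothelial-like and neutrophil-like cells the 4 genes differed by -339 CPM between TERF2DN and wild-type, against 166 CPM in microglia-like cells. That pool held them at 552 CPM in wild-type, above the 165 CPM of microglia-like cells, so it did not gauge free RNA alone. Free RNA and the TERF2DN genotype stay open, as does a difference between the animals sampled.

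In the APP/PS1;TERF2DN library the same 4 genes had a median log2 ratio to APP/PS1 of -0.72. Without the marker-bearing cells, 37.5% of APP/PS1 and 39.7% of APP/PS1;TERF2DN microglia-like cells, it was -0.57 with a median level of 181 CPM left in the lower library, which argues against other antigen-presenting cells as the whole source. Free RNA was gauged in pooled endothelial-like and neutrophil-like cells. They differed by 52.0 CPM (-6.92 to 111), against -750 CPM in microglia-like cells. That direction cannot be read, since the pool's mix of both classes differed between these libraries. The pool held the genes at 166 CPM in APP/PS1;TERF2DN and 114 CPM in APP/PS1. Both levels were smaller in size than the microglia-like difference, which argues against free RNA at that level as the whole source. MHC class I genes did not follow, with a median of 0.12. A lower MHC class II level in APP/PS1;TERF2DN microglia is a hypothesis, which staining for the protein in more animals would test; the amyloid load was not measured here.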

How the results depend on the processing

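The settings without the cycling cluster, with the low-UMI cluster and with equal cluster mixes were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library and nothing in the labels links them. With 1 library each, depth limits only the counting error. The DAM stage 2 median stayed between 1.86 and 2.62 for APP/PS1 against wild-type, between 1.39 and 2.03 for APP/PS1;TERF2DN against TERF2DN, between -0.38 and -0.14 for APP/PS1;TERF2DN against APP/PS1, and between -0.04 and 0.06 for TERF2DN against wild-type. The homeostatic median stayed between -1.02 and -0.60, -0.97 and -0.51, -0.07 and 0.13, and -0.05 and 0.01 in that order. Over single genes and the other lists, 7505 values lay within the counting or member interval of the reported value, 1710 moved outside it, and 23 reversed, counting a change of sign only for genes past the size threshold and lists with an interval clear of 0; for moves below, the cause was not tested unless given.

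Microglia-like shares in wild-type, TERF2DN, APP/PS1 and APP/PS1;TERF2DN were 71.2%, 64.6%, 74.8% and 75.2% with no cell filter, 90.6%, 90.04%, 94.8% and 94.8% with the stricter one, 92.8%, 93.3%, 92.7% and 93.5% when gated cell by cell, and 89.5%, 89.7%, 89.4% and 91.2% with the low-UMI cluster. The share in APP/PS1;TERF2DN was 93.1% with each library clustered on its own. By size factors the homeostatic median was -0.60 for APP/PS1 against wild-type and -0.51 for APP/PS1;TERF2DN against TERF2DN, which follows the shift of the all-gene median. The DAM-high shares were 0.871%, 1.35%, 40.9% and 26.9% at the 99th percentile, lower by construction, and 1.29%, 1.91%, 45.2% and 34.2% for 3 or more DAM genes. In APP/PS1 and APP/PS1;TERF2DN they were 60.3% and 48.1% without the cells highest in immediate-early genes, and 55.1% and 42.0% at 1000 UMIs. With equal cluster mixes, APP/PS1;TERF2DN against APP/PS1 gave -0.14 for DAM stage 2 and -0.0664 for homeostatic genes, the second reversed; the clusters are led by these genes, so the setting removes part of the difference by construction.

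Reversed for TERF2DN against wild-type were Camp with no cell filter (0.0634), each library on its own (0.0386), gating (0.16) and no cycling cluster (0.14), S100a8 and S100a9 with each library on its own (0.35 and 0.33), and H2-Ab1 with gating (-0.0462). Cenpa reversed with thinning (-0.10) and without the cycling cluster (-0.10), and Top2a without that cluster (-0.0296). For APP/PS1;TERF2DN against TERF2DN, H2-Eb1 and Il1b reversed with gating (-0.26 and -0.0539), Ube2c with thinning (0.0528) and without the cycling cluster (0.10), and Top2a without it (0.0091). The complement median of APP/PS1 against wild-type was 0.13 by size factors. Of the differences between both TERF2DN comparisons, that of Camp was -0.0751 with gating and -0.0716 without the cycling cluster. The proliferation median was 0.0533 as a mean over cells and 0.10 without that cluster, and Cenpf (0.0448), Top2a (0.0755) and Ube2c (0.0933) reversed without it. Top2a, Cenpf and Ube2c are among the genes that lead the cycling cluster, so that setting brings their values toward 0 by construction. Hist1h2ap leads it too, but its difference was -1.31 without that cluster, against -1.15 in the main setting. The MHC class II median gated cell by cell was 0.82 for APP/PS1 against wild-type, 0.21 for APP/PS1;TERF2DN against TERF2DN, -0.62 for APP/PS1;TERF2DN against APP/PS1 and -0.0024 for TERF2DN against wild-type.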

Other observations

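The tests of depth and dissociation for DAM genes were chosen after the result was seen, as were the border macrophage genes named here.

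Border macrophage-like cells, which sit at the brain's surfaces and vessels and were left out of the comparisons above, numbered 388 in wild-type, 215 in TERF2DN, 90 in APP/PS1 and 133 in APP/PS1;TERF2DN. Genes of this class were viewed only if they reached 200 CPM in any library. The B cell chemokine Cxcl13 stood at 33.1, 91.3, 45.4 and 340 CPM. It passed that minimum only through the APP/PS1;TERF2DN library, so its being highest there follows in part from the choice. Whether its UMIs lay in a few cells was not examined. The monocyte chemokine Ccl8 stood at 637, 413, 184 and 597 CPM, the adhesion molecule Vcam1 at 414, 498, 446 and 934 CPM, Ms4a6c at 522, 543, 640 and 1071 CPM, and Ucp2 at 373, 484, 466 and 929 CPM. Dissociation and immediate-early genes had a median log2 ratio of -0.57 in APP/PS1;TERF2DN against APP/PS1 in this class. DAM stage 2 genes had a median of 0.45 for APP/PS1 against wild-type, with Cst7 at 6.09 CPM in wild-type and 193 CPM in APP/PS1, but at 112 CPM in neutrophil-like cells of the APP/PS1 library, so carried-over microglial RNA may account for this. For APP/PS1;TERF2DN against APP/PS1 the list's median in this class was 0.28 (-0.03 to 0.42). That interval spanned both signs, and the median rests on 20 members at 50 CPM or more in this class. The -0.32 in microglia-like cells rests on 24 members, so the signs of both medians cannot be set against each other.

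DAM stage 2 genes were lower in the APP/PS1;TERF2DN than in the APP/PS1 library, with a median log2 ratio of -0.32. Depth per cell is argued against, since the median was -0.38 with cells thinned to 2000 UMIs before summing. Dissociation is as well, with -0.29 without the 25% of cells highest in immediate-early genes. Free RNA was gauged in pooled endothelial-like and neutrophil-like cells. There the list held 0.218% of UMIs in APP/PS1 and 0.360% in APP/PS1;TERF2DN, a difference of -0.142 points against 0.641 points in microglia-like cells. That direction cannot be read, since the pool's mix differed. Neutrophil-like cells gave 62689 and 175868 of its UMIs in that order, and endothelial-like cells 182520 and 203189. Both pooled levels were smaller than the 0.641 points, which argues against free RNA at that level as the whole source. Astrocyte-like cells of low depth, which held Cst7 in APP/PS1, were not part of this gauge. What stays open is whether a lower DAM state goes with TERF2DN, as a candidate explanation, or with another difference between the animals sampled. A lower plaque load and age are among these and were not measured here. The glucocorticoid exposure weighed below was not tested for DAM genes.

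Fkbp5 and Tsc22d3, higher in the APP/PS1;TERF2DN than in the APP/PS1 library, where Tsc22d3 at 8.003 CPM was also under its 25.9 CPM in wild-type, were higher there in other classes too: Fkbp5 at 23.9 and 166 CPM and Tsc22d3 at 62.1 and 155 CPM in border macrophage-like cells, and Tsc22d3 at 131 and 241 CPM in endothelial-like cells. Another mix of microglia-like clusters is argued against, since the mean log2 ratio of both genes was 1.34 with equal mixes and 1.46 without. A difference in glucocorticoid exposure between the animals sampled may account for both genes and cannot be told apart from a genotype effect: 17 other targets had a median of 0.10 (-0.01 to 0.19), at percentile 99.5 of random lists. Past the size threshold were Ddit4, at 2.03 and 11.9 CPM, and Klf9, at 3.31 and 10.3 CPM, both measured only through the APP/PS1;TERF2DN library, and in the other direction Tsc22d1, at 42.1 and 29.6 CPM. By the rule written first, an upper limit under 0.2 excluded this exposure; it was moved to open after the values were seen, because of that percentile and because targets went both ways, and time of day was moved likewise, since the clock gene gap of 0.0314 rested on 1 measured gene of the night-end list.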
